A study of Homo sapiens with 12 samples.

How the data were processed

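HK-2 cells exposed to CsA or control for 12 h or 48 h were profiled on 12 Affymetrix arrays, 3 biological replicates in each of 4 groups. The series belongs to a larger set of compounds and doses, of which CsA and its control are analysed here. The deposited values are on the log2 scale, read as such from the values themselves, which lie between 0.68 and 16.0 with array medians near 3. They were made with GCRMA, per the submitters' processing notes. GCRMA adjusts background by probe sequence, normalises arrays by quantiles and summarises probes into probe sets. The version of GCRMA and its settings are not given in the sources used here. The values were used as deposited, with no further normalization.

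Of 54675 probe sets, 62 Affymetrix control probe sets were left out, 41091 carried exactly 1 gene symbol, 1801 carried several and 11721 carried none, per the deposited probe annotation. For each of the 19775 symbols the probe set with the highest mean over the 12 arrays was used, 54 probe sets had a symbol that was not in the gene name table, and 0 symbols were updated. A gene was tested if that probe set was above 4 on at least 3 arrays of any group, which left 10650 genes. No genome build is stated with the arrays, so no coordinates are given. Arrays do not have a read depth, and the number of arrays limits the precision.

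All tests were two-sided. Differences were tested with limma 3.58.1 in R 4.3.3, as a linear model with 4 group means over all 12 arrays (8 residual degrees of freedom), moderated by eBayes without a trend, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The comparisons were CsA against control at 12 h and at 48 h, the difference between these effects, and 48 h against 12 h in controls and under CsA. Changes are log2 differences of group means with moderated standard errors. The groups, comparisons, tests, filter, gene lists, rule for named genes and most alternatives were chosen before the data were examined.

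The labels number the replicates in each group. Samples with the same number at the same time deviated together from their group means: across genes the correlations of CsA and control were 0.36, 0.52 and 0.59 at 12 h and 0.78, 0.54 and 0.74 at 48 h, and each array correlated best with its own number. The pairing therefore comes from the data, since the labels do not say what a number stands for. Between times the numbers did not pair the arrays, with correlations of same-numbered arrays between -0.14 and 0.22 under CsA and between -0.02 and 0.06 in controls. A fit with the replicate number as a block within each time (4 residual degrees of freedom) was run as an alternative, and its value is given beside a result where it changed a call.

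From textbook knowledge 34 gene lists with 716 genes were fixed. They cover ER chaperones and the unfolded protein response, the ATF4 and amino acid response, cytosolic aminoacyl-tRNA synthetases, coat proteins and ER-Golgi trafficking, NRF2 targets, cytosolic heat shock proteins, cholesterol synthesis and uptake, fatty acid synthesis, DNA replication, mitosis, p53 targets, glycolysis, hypoxia targets outside glycolysis, oxidative phosphorylation, TGF-beta targets and mesenchymal genes, collagens and matrix enzymes, epithelial junctions and keratins, proximal tubule transporters and enzymes, kidney injury markers, NF-kB targets and inflammatory cytokines, the interferon response, cyclophilins with calcineurin and NFAT, autophagy and lysosome, BCL2 family and caspases, metallothioneins, immediate early genes and MAPK feedback, cytosolic ribosomal proteins, drug efflux and xenobiotic enzymes, and glucocorticoid-responsive genes. The other 5 are markers of distal nephron and collecting duct, podocytes, fibroblasts and pericytes, endothelium, and leukocytes. The 29 lists with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, which compares a list with the other genes, adjusted over the lists within a comparison. Camera with an estimated correlation was run as an alternative, as was fry, which tests whether a list's genes move, on balance, one way and does not compare the list with other genes. Members past the threshold were counted over all genes and adjusted over the list alone.

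Named genes followed a rule. For each CsA comparison it took up to 12 rising and 12 falling genes past the threshold whose arrays did not overlap between groups, and the 4 members of each called list with the largest absolute moderated statistic, past the threshold or not. For the other comparisons it took up to 6 rising and 6 falling genes past the threshold. PPIA, PPIB, PPIF, RCAN1, HAVCR1, LCN2, DDIT3 and HSPA5 were named whatever their values. Genes outside the rule are said to have been chosen after their values were seen, and other probe sets of a named gene past the filter were checked for the opposite sign.

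The fits were tested on simulated data with the real genes and spreads and 200 changed genes. For CsA at 12 h the unpaired fit recovered 20.9%, 55.2% and 90.9% of genes changed by 0.5, 1 and 2 on the log2 scale, and 3.48% of its calls were false. With the pairs as a block it recovered 50.7%, 85.1% and 95.5% with 7.78% false. At 48 h the unpaired fit recovered 23.9%, 64.2% and 95.5% with 10.3% false calls, and 32.5% with the pairs as a block. For the time comparison in controls it recovered 35.8%, 68.7% and 95.5% with 27.7% false calls, and 4.48%, 52.2% and 84.8% with 12.2% in a fit of the 2 groups alone. Camera called a list of 25 genes shifted by 0.5 (adjusted p = 1.32e-77) and 0 of 100 random lists. Random lists do not test it on correlated genes (0.83 estimated for ER genes).

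Alternatives tried were no filter and a filter at 6, quantile normalization and centring of arrays, the mean of a gene's probe sets and all probe sets, eBayes with trend and robust moderation, estimated array weights, only the arrays of the groups compared, the replicate block over all arrays and within time, each array left out in turn, a threshold of 0.01, a test against a log2 change of 0.5 (treat), and the list tests named above. Chosen after seeing the data were the fits of the 6 arrays of a time with the pairs as a block (with and without trend and robust moderation), the fit without either 48 h array numbered 3, and the blocked list tests with an estimated correlation and by fry.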

Results

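Messenger RNA was measured on Affymetrix arrays in HK-2 cells, an immortalised line from human kidney proximal tubule, after exposure to CsA or control. CsA is read here as cyclosporine A, an immunosuppressant that binds cyclophilins, inhibits calcineurin and can harm the kidney, and its dose is not in the labels. The 12 arrays formed 4 groups with 3 biological replicates each: CsA 12 h, control 12 h, CsA 48 h and control 48 h. Array medians lay between 2.85 and 2.96 on the log2 scale, and between 38.3% and 38.8% of probe sets were above 4. The lowest correlation between arrays of a group, across probe sets, was 0.997 in each 12 h group, 0.991 in control 48 h and 0.982 in CsA 48 h, where it was that of replicates 1 and 3. The median standard deviation of a gene within a group was 0.12 in CsA 12 h, 0.12 in control 12 h, 0.21 in control 48 h and 0.29 in CsA 48 h. Arrays of CsA and control with the same replicate number and time deviated together from their group means, so a fit with these pairs as a block is given wherever it changed a call. The number of arrays limits the precision of every value.

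The first comparison asked which genes differed between CsA and control after 12 h. CREB3L2, which codes for a transcription factor anchored in the endoplasmic reticulum (ER) membrane (probe set 212345_s_at), was at 8.98 ± 0.07 under CsA and 7.53 ± 0.16 in control (log2, SD, n = 3). DNAJB9, a co-chaperone of the ER lumen (probe set 202842_s_at), was at 10.02 ± 0.25 and 8.57 ± 0.29. MANF, a secreted protein made under ER stress (probe set 202655_at), was at 11.19 ± 0.22 and 10.36 ± 0.23. Without the pairs limma called 0 of 10650 genes, with 138 at an unadjusted p under 0.05 (55 higher and 83 lower) and a smallest adjusted p of 1.00. With the pairs as a block it called 3 genes, all higher under CsA. These were CREB3L2 (2.72-fold, adjusted p = 0.025), DNAJB9 (2.74-fold, adjusted p = 0.025) and MANF (1.78-fold, adjusted p = 0.029). CREB3L2 and MANF are named because of that call, after their values were seen. Over the alternatives, many of which ignore the pairs, CREB3L2, DNAJB9 and MANF ran from 7.79e-04, 0.0015 and 0.0014 to 1.00 (adjusted p).

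In a fit of the 6 arrays at 12 h alone with the pairs as a block, chosen after the data were seen, limma called 5 genes, all higher under CsA. They were SLC7A11, the cystine transporter (adjusted p = 0.0065), CREB3L2 (0.024) and INHBE, a stress-induced inhibin subunit (0.026). The others were CTH, which makes cysteine from cystathionine (0.030), and SDF2L1, an ER chaperone cofactor (0.038). SLC7A11 differed by 1.86, 1.85 and 1.86 in the 3 pairs, CTH by 1.56, 1.29 and 1.37, and INHBE by 3.21, 3.63 and 4.09. DNAJB9 (adjusted p = 0.068) and MANF (0.070) were not called in that fit. For INHBE 1 of the 3 control arrays was below 4. These genes were chosen after their values were seen, and each had a highest adjusted p of 1.00 over the alternatives, many of which ignore the pairs. The lowest over the alternatives was 1.61e-04 for SLC7A11, 7.79e-04 for INHBE, 0.0014 for CTH and 0.0015 for SDF2L1. With a variance trend and robust moderation added to that fit, limma called 102 genes higher and 25 lower. Of these, 13 of the higher and 0 of the lower differed by at least 1 on the log2 scale.

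The list of ER chaperones and unfolded protein response genes stood higher under CsA at 12 h. Of its 25 tested members 23 had values above 0 and 2 below, with a median log2 change of 0.48. Camera called the list (adjusted p = 3.43e-09, adjusted p = 0.81 with an estimated correlation). HSPA5, the main Hsp70 chaperone of the ER, was at 14.49 ± 0.25 under CsA and 13.61 ± 0.42 in control (log2, SD, n = 3), a change of 0.88 with a standard error of 0.51. Changes of XBP1, a transcription factor of the unfolded protein response, and DNAJC10, an ER disulfide reductase, were 0.68 (SE 0.31) and 0.51 (SE 0.25). No member passed the unpaired limma test over all genes or when adjusted over the list alone (0 and 0 of 25). When the pairs were a block 2 members passed over all genes and 21 when adjusted over the list alone. The list was then called with an estimated correlation (adjusted p = 0.022) and by fry (adjusted p = 0.0013). In the 6 arrays at 12 h alone with the pairs as a block both of these calls were lost (adjusted p = 0.46 with an estimated correlation, 0.059 by fry). The list's adjusted p ran from 1.09e-31 to 1.00 over the alternatives. Its median difference was 0.56, 0.45 and 0.46 in the 3 pairs, and 22 members were above 0 in every pair.

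Genes of the ATF4 and amino acid response, which cells switch on when amino acids are short or the ER is stressed, formed the list with the lowest adjusted p at 12 h. All 28 tested members had values above 0, with a median of 0.65 (camera, adjusted p = 3.52e-18, adjusted p = 0.81 with an estimated correlation, 1.19e-36 to 1.00 over the alternatives). ALDH1L2, a mitochondrial folate enzyme, differed by 2.74 (SE 1.26), CHAC1, which breaks down glutathione, by 1.99 (SE 0.90), and ATF4, the transcription factor of the response, by 0.68 (SE 0.26). No member passed the unpaired test over all genes or when adjusted over the list alone (0 and 0 of 28), while 2 passed over the list alone with the pairs as a block. The medians in the 3 pairs were 0.77, 0.41 and 0.63, and 27 members were above 0 in every pair. The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids and are partly under ATF4 control, had 11 of 15 members above 0 and a median of 0.35 (adjusted p = 1.79e-04, adjusted p = 0.81 with an estimated correlation, 3.60e-11 to 1.00 over the alternatives). Their members AARS1, YARS1, CARS1 and LARS1 differed by 0.86 (SE 0.61), 0.62 (SE 0.44), 0.60 (SE 0.48) and 0.35 (SE 0.21).

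**Figure D1:**
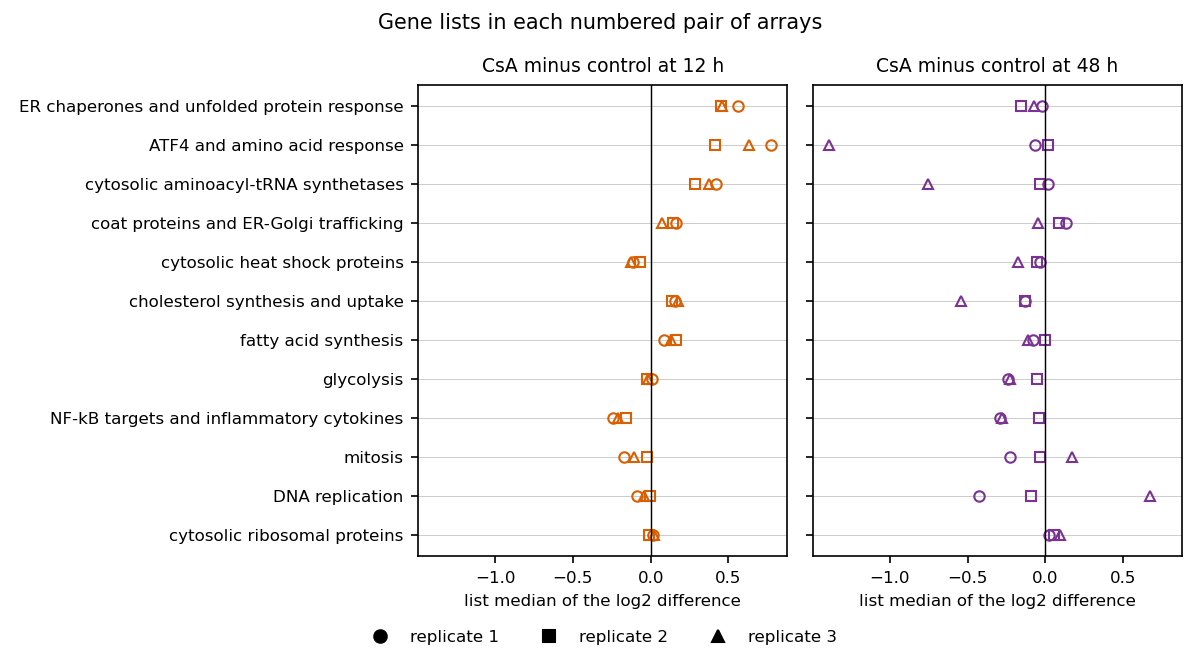
Median log2 difference between CsA and control over the tested members of 12 gene lists, in each of the 3 pairs at 12 h and at 48 h, with markers giving the replicate number. At 12 h the ER list had medians of 0.56, 0.45 and 0.46, and at 48 h the ATF4 list had medians of -0.07, 0.02 and -1.39.

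Coat proteins and ER-Golgi trafficking genes, which carry cargo out of the ER, were also higher at 12 h, with 22 of 23 members above 0 and a median of 0.12 (adjusted p = 3.17e-05, adjusted p = 0.81 with an estimated correlation, 2.05e-09 to 1.00 over the alternatives). SEC24D, a cargo adaptor of COPII vesicles, differed by 0.72 (SE 0.54) and TMED10, a cargo receptor, by 0.36 (SE 0.19). Cholesterol synthesis and uptake genes had 15 of 18 members above 0 with a median of 0.15 (adjusted p = 0.0063, adjusted p = 0.81 with an estimated correlation, 2.91e-07 to 1.00 over the alternatives). MVD was at 0.54 (SE 0.26) and INSIG1 at 0.33 (SE 0.22). For fatty acid synthesis 9 of 10 members were above 0 with a median of 0.14 (adjusted p = 0.011, adjusted p = 0.81 with an estimated correlation, 1.97e-04 to 1.00 over the alternatives). ACSS2 was at 0.38 (SE 0.38) and SCD at 0.26 (SE 0.13). Cytosolic heat shock proteins went the other way. All 11 members were below 0 with a median of -0.12 (adjusted p = 0.0026, adjusted p = 0.24 with an estimated correlation, 2.31e-05 to 0.58 over the alternatives). HSPA4L was at -0.32 (SE 0.11) and HSP90AA1 at -0.13 (SE 0.12). NF-kB targets and inflammatory cytokines had 13 of 15 members below 0 with a median of -0.21 (adjusted p = 0.027, adjusted p = 0.81 with an estimated correlation, 2.40e-04 to 1.00 over the alternatives). Among them RELB was at -0.61 (SE 0.37) and NFKB1 at -0.21 (SE 0.21). In these 5 lists and the tRNA synthetases 0 members passed the unpaired test over all genes, and 0 when adjusted over the list alone. In the blocked fit 2 coat protein genes and 2 cholesterol genes passed when adjusted over the list alone.

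Some calls were lost when 1 array at 12 h was left out and its partner kept. For cholesterol it was CsA replicate 1 (adjusted p = 0.070), CsA replicate 2 (0.13) or control replicate 3 (0.50). For fatty acids it was CsA replicate 2 (0.30) or control replicate 3 (0.60). For NF-kB it was CsA replicate 2 (0.61), control replicate 1 (0.18) or control replicate 3 (0.48). Pair medians were 0.15, 0.14 and 0.18 for cholesterol, 0.09, 0.17 and 0.13 for fatty acids and -0.24, -0.16 and -0.21 for NF-kB. The block kept these calls and added 2 list calls at 12 h. Mitosis genes had 24 of 24 members below 0 and a median of -0.11 (adjusted p = 0.0013, adjusted p = 0.70 with an estimated correlation in the blocked fit, and 0.28 without the block, 4.13e-06 to 1.00 over the alternatives). No mitosis gene passed in the blocked fit over all genes or over the list alone (0 and 0). Autophagy and lysosome genes had 18 of 25 members above 0 and a median of 0.08 (adjusted p = 0.031, adjusted p = 0.63 with an estimated correlation in the blocked fit, and 0.12 without the block, 0.014 to 1.00 over the alternatives). In that list 0 members passed over all genes with the block and 1 over the list alone.

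List medians at 12 h moved by over 1.5 times with some 12 h arrays left out and partners kept. The cholesterol median of 0.15 was 0.09 without CsA replicate 1, 0.26 without CsA replicate 3 and 0.04 without control replicate 3. The fatty acid median of 0.14 was 0.05 without CsA replicate 2, 0.22 without CsA replicate 3 and 0.03 without control replicate 3. The NF-kB median of -0.21 was -0.08 without CsA replicate 2, -0.36 without control replicate 2 and -0.10 without control replicate 3. The mitosis median was -0.06 without CsA replicate 1 and -0.17 without replicate 2. The autophagy median was 0.03 without CsA replicate 1, 0.02 without control replicate 2 and 0.05 without control replicate 3. Among the members given, ACSS2, INSIG1, SCD, RELB and NFKB1 were at 0.09, 0.20, 0.15, -0.33 and -0.12 without control replicate 3.

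Of the genes named whatever their values, the cyclophilins PPIA, PPIB and PPIF, proteins that bind CsA, differed by -0.0031 (SE 0.093), 0.48 (SE 0.30) and -0.11 (SE 0.24). RCAN1, a calcineurin regulator, differed by 0.06 (SE 0.29), DDIT3, a stress-induced transcription factor, by 0.70 (SE 0.85), and the kidney injury markers HAVCR1 and LCN2 by 0.0014 (SE 0.26) and -0.09 (SE 0.59). None of these genes passed the test over all 12 arrays at 12 h, with or without the block (adjusted p = 1.00 for each without it). In the 12 h arrays alone with the block, trend and robust moderation, PPIB (adjusted p = 0.036) and DDIT3 (0.023) passed, each higher under CsA. HSPA5 (0.0018), XBP1 (0.0084), DNAJC10 (0.0043), ALDH1L2 (0.0036), CHAC1 (0.0050) and ATF4 (0.0015) also passed higher there. So did AARS1 (0.0043), YARS1 (0.0065), CARS1 (0.031), LARS1 (0.036), SEC24D (0.014), TMED10 (0.0088), INSIG1 (0.020) and SCD (0.035). Each gene named as passing was at 1.00 at its highest over the alternatives, many of which ignore the pairs.

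The comparison of CsA with control at 48 h asked the same question after longer exposure. The ATF4 list stood lower under CsA, with 28 of 28 tested members below 0 and a median of -0.49 (camera, adjusted p = 3.85e-07, adjusted p = 0.94 with an estimated correlation, 2.27e-11 to 0.94 over the alternatives). ATF3, a stress-induced transcription factor, differed by -1.48 (SE 0.83), STC2, a secreted stanniocalcin, by -1.01 (SE 0.56), and MTHFD2, a mitochondrial folate enzyme, by -0.52 (SE 0.27). The list's median was -0.07, 0.02 and -1.39 in the 3 pairs. Without CsA 48 h replicate 3 the list turned to higher and lost its call (adjusted p = 0.54). Without that array the values of ATF3, STC2 and MTHFD2 were -0.31, -0.24 and -0.15. The tRNA synthetases had 14 of 15 members below 0 and a median of -0.24 (adjusted p = 0.026, adjusted p = 0.96 with an estimated correlation, 0.0011 to 0.96 over the alternatives). CARS1 was at -0.56 (SE 0.48) and TARS1 at -0.39 (SE 0.24). That list turned to higher without CsA 48 h replicate 3 (adjusted p = 0.17) and lost its call without control 48 h replicate 1 (0.23) or control 48 h replicate 2 (0.14). Without the pairs limma called 0 of 10650 genes at 48 h, with 263 at an unadjusted p under 0.05, again below a share of 0.05. Of these, 120 were higher and 143 lower. With the block limma also called 0, with 1308 under 0.05.

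Cholesterol synthesis and uptake genes were lower at 48 h, with 17 of 18 members below 0 and a median of -0.23 (adjusted p = 8.14e-04, adjusted p = 0.85 with an estimated correlation, 3.29e-07 to 0.93 over the alternatives). NSDHL and HSD17B7, enzymes of sterol synthesis, differed by -0.44 (SE 0.18) and -0.44 (SE 0.19), and SQLE, the squalene epoxidase, by -0.43 (SE 0.27). Glycolysis genes had 16 of 18 members below 0 and a median of -0.19 (adjusted p = 8.14e-04, adjusted p = 0.85 with an estimated correlation, 2.65e-06 to 0.93 over the alternatives). SLC2A1, a glucose transporter, was at -0.49 (SE 0.24), LDHA at -0.24 (SE 0.13) and PGK1 at -0.24 (SE 0.11), of which another probe set had the opposite sign. NF-kB targets had 12 of 15 members below 0 and a median of -0.21 (adjusted p = 0.0084, adjusted p = 0.85 with an estimated correlation, 0.0026 to 0.93 over the alternatives). TNFAIP3, a feedback inhibitor of NF-kB, was at -0.66 (SE 0.30) and CXCL2, a neutrophil chemokine, at -0.65. Ribosomal protein genes had 22 of 23 members above 0 with a median of 0.06 (adjusted p = 0.0017, adjusted p = 0.85 with an estimated correlation, 4.28e-12 to 0.87 over the alternatives). RPL18 was at 0.15 (SE 0.082) and RPL3 at 0.14 (SE 0.079). Coat proteins had 14 of 23 above 0 with a median of 0.05 (adjusted p = 0.042, adjusted p = 0.96 with an estimated correlation, 1.18e-05 to 0.96 over the alternatives). COPZ1 was at 0.28 (SE 0.15) and LMAN1 at 0.30 (SE 0.24). Heat shock proteins had 9 of 11 below 0 with a median of -0.11 (adjusted p = 0.036, adjusted p = 0.85 with an estimated correlation, 0.076 with the pairs as a block, 0.0038 to 0.85 over the alternatives). HSPH1 was at -0.35 and CRYAB at -0.34.

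In all 8 lists called at 48 h, 0 members passed the unpaired limma test over all genes and 0 when adjusted over the list alone. In the blocked fit 4 NF-kB targets and 1 heat shock gene passed when adjusted over the list alone, all lower. Without CsA 48 h replicate 1 the calls of the cholesterol, glycolysis and NF-kB lists were lost (adjusted p = 0.31 for each). The coat protein list then turned to lower (0.31) and the heat shock list lost its call (0.17). Without control 48 h replicate 3 the calls of the cholesterol (adjusted p = 0.089), glycolysis (0.53), NF-kB (0.089), ribosomal (0.089) and heat shock (0.15) lists were lost. The coat protein list turned to lower without that array (0.95). The heat shock call was also lost without CsA 48 h replicate 2 (adjusted p = 0.18) or control 48 h replicate 1 (0.077). The coat protein call was lost without control 48 h replicate 2 (0.19). The pairs as a block added 3 calls. They were interferon response genes, higher (13 of 18 above 0, median 0.12, adjusted p = 0.0079), immediate early genes, lower (13 of 16 below 0, median -0.19, adjusted p = 0.0067) and markers of fibroblasts and pericytes, lower (5 of 6 below 0, median -0.25, adjusted p = 0.022). All 3 calls were lost in the blocked fit with another list test (adjusted p = 0.51 with an estimated correlation for each). With the block 2, 2 and 3 of their members passed over the list alone and 0 over all genes. Without the block their adjusted p were 0.13, 0.081 and 0.31. Over the alternatives they ran from 0.0050 to 0.96, from 4.40e-07 to 0.96 and from 0.022 to 0.94. Without the block the interferon list was also called when CsA 48 h replicate 2 (adjusted p = 0.017) or control 48 h replicate 1 (0.032) was left out. The immediate early list was called lower when CsA 48 h replicate 2 (0.0031), CsA 48 h replicate 3 (0.0092) or control 48 h replicate 1 (7.10e-05) was.

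List medians at 48 h moved by over 1.5 times with some arrays left out. The ATF4 median of -0.49 was -0.77, -0.83 and 0.06 without CsA 48 h replicates 1, 2 and 3 in turn, and the tRNA synthetase median of -0.24 was -0.52, -0.40 and 0.15. The latter was also -0.11 without control 48 h replicate 1 and -0.39 without control 48 h replicate 3. The coat protein median of 0.05 was -0.19, 0.10 and 0.23 without CsA 48 h replicates 1, 2 and 3, and 0.21, -0.0022 and -0.04 without the controls of these numbers. The cholesterol median of -0.23 was -0.10 without CsA 48 h replicate 1, -0.45 without CsA 48 h replicate 2 and -0.45 without control 48 h replicate 1. The glycolysis median of -0.19 was -0.07 without CsA 48 h replicate 1 and -0.05 without control 48 h replicate 3, where the ribosomal median of 0.06 was 0.04. The interferon median was 0.07, 0.30 and 0.06 without CsA 48 h replicates 1, 2 and 3 and 0.05 without control 48 h replicate 2. The immediate early median was 0.17 without CsA 48 h replicate 1, -0.36 without CsA 48 h replicate 2, and -0.41, -0.07 and -0.05 without control 48 h replicates 1, 2 and 3. The fibroblast marker median was -0.09 without CsA 48 h replicate 1 and -0.11 without control 48 h replicate 3.

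Values of single genes at 48 h moved too. CARS1, TARS1, NSDHL, HSD17B7, SLC2A1 and CXCL2 were at 0.15, -0.09, -0.29, -0.06, -0.15 and -0.18 without CsA 48 h replicate 3. SQLE, COPZ1 and LMAN1 were at -0.21, 0.13 and 0.01 without CsA 48 h replicate 1, and LDHA, PGK1 and CRYAB at -0.12, -0.13 and -0.20 without control 48 h replicate 3. HSPH1 was at -0.21 without control 48 h replicate 2.

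The ER list, with a median of 0.48 at 12 h, had 4 of 25 members above 0 at 48 h and a median of -0.09 (adjusted p = 0.63, 3.50e-05 to 0.96 over the alternatives). It was called higher without CsA 48 h replicate 3 (adjusted p = 0.0028) or control 48 h replicate 1 (0.032), and lower without CsA 48 h replicate 1 (0.0016) or control 48 h replicate 3 (3.50e-05). Each of these fits left an array without the partner with which it deviated together. The list's medians in the 3 pairs were -0.02, -0.15 and -0.07, and with the pair numbered 3 left out the median was -0.11 (adjusted p = 0.35, against 0.089 with the pairs as a block). HSPA5 differed by -0.38 and DDIT3 by -1.02 at 48 h. In the 3 pairs HSPA5 differed by 0, -0.22 and -0.93 and DDIT3 by -0.09, -0.11 and -2.86. Their values were 0.27 and 0.26 without CsA 48 h replicate 3. The cyclophilins PPIA, PPIB and PPIF differed by -0.03 (SE 0.093), 0.19 (SE 0.30) and -0.15 (SE 0.24), RCAN1 by -0.47 (SE 0.29), HAVCR1 by -0.09 and LCN2 by 0.33 (SE 0.59). The value of RCAN1 was -0.06 without CsA 48 h replicate 3. PPIA, PPIB, PPIF, HAVCR1 and LCN2 were at 0.03, -0.07, 0.08, 0.13 and -0.30 without CsA 48 h replicate 1. The first 4 of them were at 0.03, -0.09, 0.05 and 0.19 without control 48 h replicate 3. No named gene passed the test at 48 h (adjusted p = 1.00 for each, and above 0.05 with the pairs as a block).

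The difference between the CsA effects at 48 h and 12 h was tested itself, because a call at 1 time alone does not show that the times differ. All 28 ATF4 response genes had a lower CsA effect at 48 h than at 12 h, with a median difference of -1.09 (camera, adjusted p = 5.31e-22, adjusted p = 0.93 with an estimated correlation, 6.86e-26 to 0.97 over the alternatives). All 25 ER genes did so too, with a median of -0.67 (adjusted p = 1.86e-05, adjusted p = 0.93 with an estimated correlation, 1.19e-20 to 0.97 over the alternatives). The tRNA synthetases had 14 of 15 differences below 0 with a median of -0.61 (adjusted p = 1.34e-05). Cholesterol genes had 16 of 18 with a median of -0.43 (adjusted p = 3.35e-06) and glycolysis genes 16 of 18 with a median of -0.15 (adjusted p = 0.018). These 3 lists were each at adjusted p = 0.93 with an estimated correlation. Over the alternatives they ran from 3.86e-07, 1.65e-10 and 7.36e-05 to 0.97 each. The ER call was lost without CsA 48 h replicate 3 (adjusted p = 0.20) or control 48 h replicate 1 (0.25). The glycolysis call was lost without CsA 48 h replicate 1 (0.59) or control 48 h replicate 3 (0.78), with medians of -0.03 and -0.02. The ER median was -0.06 and -0.13 without the 2 arrays that ended its call, -1.19 without CsA 48 h replicate 1, -1.22 without control 48 h replicate 3 and -0.63 without both 48 h arrays numbered 3. The ATF4 and tRNA synthetase medians were -0.61 and -0.13 without CsA 48 h replicate 3. The cholesterol median was -0.28 without CsA 48 h replicate 1 and -0.67 without control 48 h replicate 1. Limma called 0 genes, with 164 at an unadjusted p under 0.05 (80 higher and 84 lower). In these 5 lists 0 members passed over all genes or when adjusted over the list alone.

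Limma with the pairs as a block again called 0 genes for the difference (967 at an unadjusted p under 0.05). In that fit 19 ER genes, 19 ATF4 response genes and 4 cholesterol genes passed when adjusted over the list alone. The block also added fatty acid synthesis (adjusted p = 0.041, and 0.14 without it), hypoxia targets outside glycolysis (0.037, and 0.059), autophagy and lysosome (0.028, and 0.059) and immediate early genes (0.011, and 0.11), all lower at 48 h. With the block these 4 calls were lost at adjusted p = 0.75, 0.84, 0.75 and 0.59 with an estimated correlation, and 0, 0, 0 and 1 of their members passed over the list alone. Over the alternatives these 4 lists ran from 0.0037, 0.0031, 0.017 and 5.96e-07 to 0.97 each. Without the block, leaving out 1 array also called them lower. For fatty acid synthesis the arrays were CsA 12 h replicate 3 (adjusted p = 0.038), CsA 48 h replicate 2 (0.035), control 12 h replicate 1 (0.049), control 12 h replicate 2 (0.048) and control 48 h replicate 1 (0.0037). For hypoxia targets they were CsA 12 h replicate 2 (0.045), CsA 48 h replicate 1 (0.0031), control 12 h replicate 1 (0.047), control 48 h replicate 2 (0.011) and control 48 h replicate 3 (0.039). For autophagy genes they were CsA 12 h replicate 2 (0.045), CsA 12 h replicate 3 (0.047), CsA 48 h replicate 1 (0.027), CsA 48 h replicate 2 (0.035), control 12 h replicate 1 (0.047) and control 48 h replicate 3 (0.017). For immediate early genes they were CsA 48 h replicate 2 (0.0024), CsA 48 h replicate 3 (0.011) and control 48 h replicate 1 (1.65e-04).

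Control cells at 48 h were compared with control cells at 12 h to give the change with culture time, the background for both CsA comparisons. Genes of the ATF4 response rose with time in controls, with 28 of 28 members above 0 and a median of 1.98 (camera, adjusted p = 1.09e-10, adjusted p = 0.90 with an estimated correlation, 0.033 by fry, 6.38e-16 to 0.90 over the alternatives). Of these, 22 passed over all genes and 27 when adjusted over the list alone. DDIT3 rose from 8.44 ± 0.14 to 13.25 ± 0.66 (log2, SD, n = 3, adjusted p = 0.0046). ATF3 rose from 6.51 ± 0.82 to 11.87 ± 0.29 (adjusted p = 0.0026) and CTH from 7.25 ± 0.39 to 11.69 ± 0.47 (adjusted p = 0.0087). INHBE rose by 7.47 (SE 1.48, adjusted p = 0.0075) from 4.24 ± 1.35, with 1 of 3 arrays at 12 h below 4. PLA1A, a phospholipase, rose by 4.57 (SE 0.73, adjusted p = 0.0030) from a level below 4 on all arrays at 12 h, and ERN1, the ER stress sensor IRE1, by 3.92 (SE 0.86, adjusted p = 0.011).

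Several genes fell with time in controls. SOX9, a transcription factor switched on in injured and regenerating tubules, fell from 8.66 ± 0.24 to 4.92 ± 0.06 (log2, SD, n = 3, 13.3-fold, adjusted p = 1.94e-04). TXNIP, a thioredoxin inhibitor whose transcription follows glucose, fell by 5.16 (SE 1.12, adjusted p = 0.011) to a level below 4 on all 3 arrays. TNFAIP6, a matrix-binding protein induced by inflammation, fell by 4.72 (SE 0.73, adjusted p = 0.0026) to 4.02 ± 1.15. SLN, the small membrane protein sarcolipin, fell by 4.76 (SE 1.34, adjusted p = 0.028), NAV3, a microtubule-binding protein, fell by 3.30 (SE 0.58, adjusted p = 0.0046), and MCM10, a replication factor, fell by 3.16 (SE 0.79, adjusted p = 0.018). The SLN call was lost without control 12 h replicate 1 (adjusted p = 0.074), replicate 2 (0.062) or replicate 3 (0.087), or control 48 h replicate 1 (0.10) or replicate 2 (0.094). The MCM10 call was lost without control 12 h replicate 1 (adjusted p = 0.052), replicate 2 (0.053) or replicate 3 (0.057), or control 48 h replicate 1 (0.069). Over the alternatives SLN ran from 3.63e-05 to 0.10 and MCM10 from 5.49e-05 to 0.069.

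**Figure D2:**
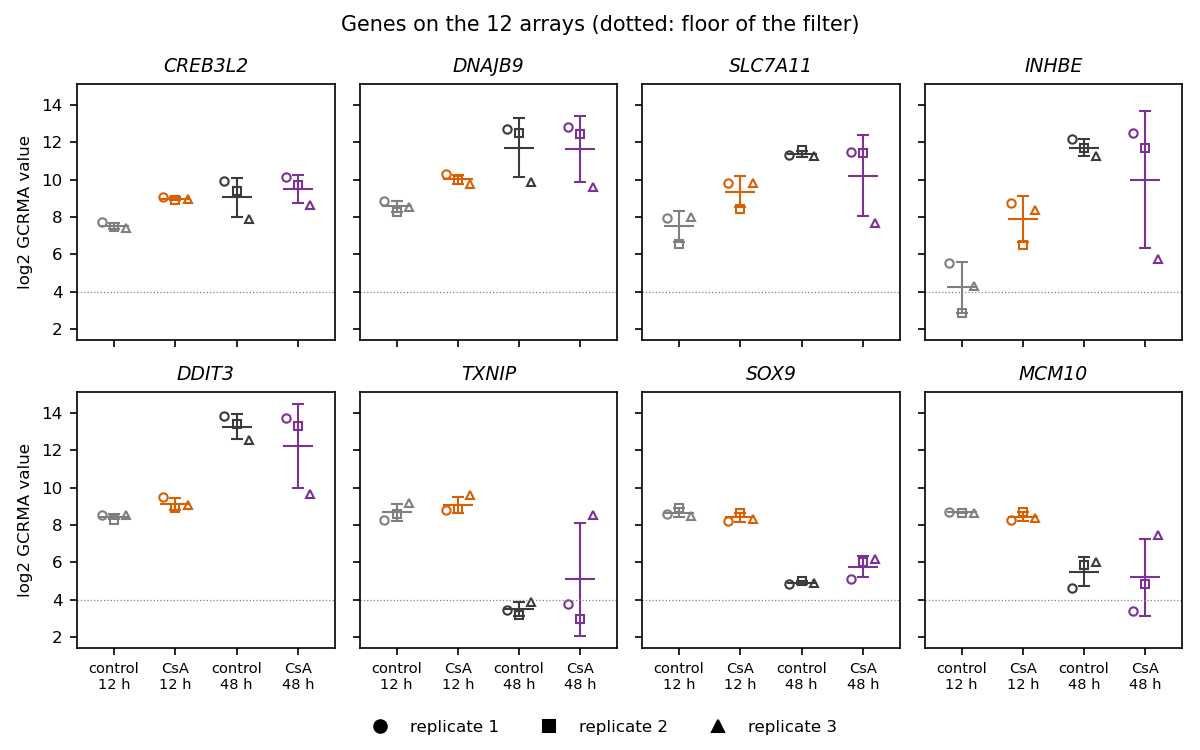
Log2 values of 8 genes on the 12 arrays in the 4 groups, with points for the replicates, bars for the group mean and standard deviation, and a dotted line at 4. SOX9 fell from 8.66 to 4.92 between control 12 h and control 48 h, and CREB3L2 at 12 h was at 8.98 under CsA and 7.53 in control.

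ER chaperones and unfolded protein response genes rose in controls, 25 of 25 above 0 with a median of 1.19 (adjusted p = 3.18e-05, adjusted p = 0.90 with an estimated correlation, 1.05e-09 to 0.90 over the alternatives). Of its members 7 passed over all genes and 8 when adjusted over the list alone. Relative to the 12 h control mean the list stood at 2.01, 1.31 and 0.30 on the 3 control 48 h arrays. Its median was 0.74 without control 48 h replicate 1 and 1.83 without replicate 3. HSPA5 rose by 1.57 (SE 0.51, adjusted p = 0.046). That call was kept only without CsA 48 h replicate 1, CsA 48 h replicate 3 or control 48 h replicate 3 among the arrays left out in turn. It was otherwise lost with adjusted p of up to 0.14 (without control 48 h replicate 1), and also without the filter (0.11, 3.42e-04 to 0.14 over the alternatives). Autophagy and lysosome genes rose, with a median of 0.49 (adjusted p = 3.18e-05, adjusted p = 0.90 with an estimated correlation, 3.41e-07 to 0.90 over the alternatives). Of them 10 passed higher over all genes, and 13 higher and 1 lower adjusted over the list alone. Mitosis genes fell, 24 of 24 below 0 with a median of -1.25 (adjusted p = 4.87e-08, adjusted p = 0.90 with an estimated correlation, 1.50e-12 to 0.90 over the alternatives). Of the mitosis genes 18 passed over all genes and 23 adjusted over the list alone. DNA replication genes fell, 26 of 27 below 0 with a median of -1.16 (adjusted p = 3.35e-06, adjusted p = 0.90 with an estimated correlation, 1.05e-09 to 0.90 over the alternatives). Of the replication genes 11 passed over all genes and 17 adjusted over the list alone. Cytosolic heat shock proteins fell, 10 of 11 below 0 with a median of -0.37 (adjusted p = 9.93e-04, adjusted p = 0.18 with an estimated correlation, 1.21e-06 to 0.18 over the alternatives). Of these, 1 passed higher and 5 lower over all genes, and 1 higher and 7 lower adjusted over the list alone. Hypoxia targets outside glycolysis rose, with a median of 0.54 (adjusted p = 0.019, adjusted p = 0.90 with an estimated correlation, 0.0043 to 0.90 over the alternatives). Here 7 passed higher and 1 lower over all genes, and 8 and 2 over the list alone.

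Coat proteins were the last list called in controls, with a median of 0.28 (adjusted p = 0.047, adjusted p = 0.90 with an estimated correlation, 0.0037 to 0.90 over the alternatives). In that list 1 member passed over all genes and 0 adjusted over the list alone. The coat protein call was lost without CsA 12 h replicate 2 (adjusted p = 0.053), CsA 12 h replicate 3 (0.052), CsA 48 h replicate 2 (0.061), control 12 h replicate 1 (0.084), control 12 h replicate 2 (0.061) or control 48 h replicate 1 (0.33). The coat protein median was 0.14 without control 48 h replicate 1 and 0.44 without replicate 3. The hypoxia call was lost without control 48 h replicate 1 (0.060). Over all genes limma called 2749, 1316 higher and 1433 lower at 48 h, of which 522 and 413 changed by at least 1 on the log2 scale. A simulation of 200 changed genes (27.7% false calls) gives no such share here. Left-out arrays moved the counts by over 1.5 times. Higher and lower genes numbered 783 and 771 without control 12 h replicate 1, 659 and 817 without replicate 2 and 655 and 629 without replicate 3. They numbered 685 and 723 without control 48 h replicate 1 and 708 and 713 without replicate 2. Without CsA 48 h replicate 3, which enters the estimate of the spread, 2002 genes were higher. Of the genes named whatever their values, PPIA, PPIB, PPIF, RCAN1, HAVCR1 and LCN2 changed by -0.11, 0.73, -0.57, 0.69, -0.50 and 0.35 and did not pass (adjusted p = 0.38, 0.097, 0.10, 0.10, 0.18 and 0.68). PPIA was at -0.05, PPIB at 0.44, PPIF at -0.37, HAVCR1 at -0.28 and LCN2 at -0.17 without control 48 h replicate 1. LCN2 was at 0.59 without replicate 2, and LCN2 at 0.63 and HAVCR1 at -0.78 without replicate 3. RCAN1 passed without CsA 48 h replicate 3 (adjusted p = 0.0043), and PPIB (0.030), PPIF (0.039) and HAVCR1 (0.036) passed without control 48 h replicate 3. Over the alternatives RCAN1 ran from 0.0013 to 0.25, PPIB from 0.0052 to 0.31, PPIF from 0.0043 to 0.32 and HAVCR1 from 0.0043 to 0.50.

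CsA cells at 48 h were compared with CsA cells at 12 h to give the change with time under CsA. PRKCB, a protein kinase C, rose by 3.21 (SE 0.47, adjusted p = 0.0052), PLA1A by 3.30 (SE 0.73, adjusted p = 0.019), DDIT3 by 3.09 (SE 0.85, adjusted p = 0.039) and ATF3 by 2.89 (SE 0.83, adjusted p = 0.045). SLC44A5, of a choline transporter family, rose by 3.04 (SE 0.52, adjusted p = 0.0072) and DORIP1 by 3.00 (SE 0.36, adjusted p = 0.0039), each from a level below 4 on all arrays at 12 h. TNFAIP6 fell by 4.54 (SE 0.73, adjusted p = 0.0059), TXNIP fell by 3.97 (SE 1.12, adjusted p = 0.042) and NAV3 fell by 3.88 (SE 0.58, adjusted p = 0.0053) to below 4 on all arrays. MCM10 fell by 3.24 (SE 0.79, adjusted p = 0.026), ZBED2, a zinc finger protein, fell by 3.21 (SE 0.55, adjusted p = 0.0072) and FOSL1, an AP-1 subunit, fell by 2.74 (SE 0.47, adjusted p = 0.0072). TXNIP at CsA 48 h was below 4 on 2 of 3 arrays and at 8.55 in replicate 3.

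Of these 12 genes, NAV3 and SLC44A5 kept their calls with only the 6 arrays of the 2 groups in the fit, and the others had adjusted p between 0.058 (PRKCB) and 0.17 (TXNIP). ATF3 kept its call only without CsA 48 h replicate 3 among the arrays left out in turn, DDIT3 kept it only without that array, control 48 h replicate 1 or control 48 h replicate 3, and TXNIP only without that array or control 48 h replicate 3. Their adjusted p reached 0.15, 0.13 and 0.14 without CsA 48 h replicate 1. Over the alternatives they ran from 4.25e-04 to 0.15, from 1.91e-05 to 0.15 and from 4.44e-05 to 0.17. MCM10 lost its call without CsA 12 h replicate 1 (adjusted p = 0.074), replicate 2 (0.084) or replicate 3 (0.080), or CsA 48 h replicate 1 (0.070) or replicate 2 (0.075). PLA1A lost it without CsA 12 h replicate 1 (adjusted p = 0.057) or replicate 3 (0.074), or CsA 48 h replicate 1 (0.062) or replicate 2 (0.056). SLC44A5 lost it with estimated array weights (adjusted p = 0.052, 4.09e-04 to 0.052 over the alternatives). Of the genes named whatever their values, HSPA5, PPIA, PPIB, PPIF, RCAN1, HAVCR1 and LCN2 changed by 0.30, -0.14, 0.44, -0.61, 0.16, -0.59 and 0.77 and did not pass (adjusted p = 0.71, 0.32, 0.33, 0.11, 0.73, 0.15 and 0.38). They were at -0.11, -0.08, 0.17, -0.38, 0.04, -0.37 and 0.14 without CsA 48 h replicate 1. HSPA5 was at 0.06 and RCAN1 at -0.13 without replicate 2, and HSPA5 at 0.95, RCAN1 at 0.58 and LCN2 at 1.22 without replicate 3. LCN2 was at 0.46 without CsA 12 h replicate 1, HSPA5 at 0.16 and PPIB at 0.29 without replicate 2, and RCAN1 at 0.10 without replicate 3. PPIF (adjusted p = 0.031), RCAN1 (0.017) and HAVCR1 (0.034) passed without CsA 48 h replicate 3, and HSPA5 without both 48 h arrays numbered 3 (0.013). Over the alternatives PPIF ran from 0.014 to 0.34, RCAN1 from 0.016 to 0.96, HAVCR1 from 0.0055 to 0.42 and HSPA5 from 0.013 to 0.96.

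Mitosis genes fell with time under CsA, with a median of -1.22 (adjusted p = 9.16e-09, adjusted p = 0.83 with an estimated correlation, 9 members passing over all genes and 22 adjusted over the list alone). DNA replication genes fell with a median of -1.14 (adjusted p = 8.45e-07, 4 and 21) and cholesterol genes with a median of -0.70 (adjusted p = 5.86e-04, 6 and 11), each at adjusted p = 0.83 with an estimated correlation. Cytosolic heat shock proteins fell with a median of -0.58 (adjusted p = 2.18e-04, adjusted p = 0.087 with an estimated correlation, 6 passing lower over all genes, and 1 higher and 7 lower over the list alone). Glycolysis genes fell with a median of -0.30 (adjusted p = 0.021, adjusted p = 0.83 with an estimated correlation, 5 passing lower over all genes, and 2 higher and 7 lower over the list alone). NF-kB targets had a median of -0.37 (adjusted p = 0.042, 1 and 1). Immediate early genes, 15 of 16 below 0, had a median of -0.37 (adjusted p = 0.032, 2 and 2). Both were at adjusted p = 0.83 with an estimated correlation. Autophagy and lysosome genes rose with a median of 0.42 (adjusted p = 3.38e-04, adjusted p = 0.83 with an estimated correlation, 6 passing higher over all genes, and 9 higher and 1 lower over the list alone). ATF4 response genes stood higher with a median of 0.48 (adjusted p = 0.0077, adjusted p = 0.84 with an estimated correlation, 5 and 5). Ribosomal proteins had a median of 0.10 (adjusted p = 0.016, 1 and 1). The p53 targets had a median of 0.31 (adjusted p = 0.045, 2 higher and 1 lower over all genes, and 5 and 1 over the list alone). Both were at adjusted p = 0.83 with an estimated correlation. In 3 more called lists 0 members passed, over all genes or over the list alone. Metallothioneins, which bind zinc and copper, stood lower with a median of -0.90 (adjusted p = 0.019, adjusted p = 0.83 with an estimated correlation). ER genes stood higher with a median of 0.54 (adjusted p = 0.016) and coat proteins with a median of 0.28 (adjusted p = 0.045), each at adjusted p = 0.84 with an estimated correlation. These 3 calls were lost without CsA 48 h replicate 1 (adjusted p = 0.12, 0.34 and 0.62), and that of the coat proteins also without CsA 12 h replicate 2 (0.067) or replicate 3 (0.064). Fry called heat shock (4.17e-05), ribosomal (0.0053) and autophagy genes (0.028). The lowest adjusted p of the 14 lists over the alternatives lay between 3.80e-14 (mitosis) and 0.016 (NF-kB targets), and the highest between 0.087 (heat shock) and 0.84.

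Other calls among these lists were lost when 1 array was left out. Without CsA 48 h replicate 1 they were ATF4 (adjusted p = 0.10), p53 targets (0.30), glycolysis (0.12), immediate early genes (0.34) and NF-kB targets (0.16). Without CsA 48 h replicate 2 it was ATF4 (adjusted p = 0.17), and without CsA 48 h replicate 3 ribosomal proteins (0.084), p53 targets (0.084) and NF-kB targets (0.066). The NF-kB call was also lost without CsA 12 h replicate 1 (adjusted p = 0.053) or replicate 3 (0.11). The p53 call was lost without CsA 12 h replicate 2 (adjusted p = 0.082), CsA 12 h replicate 3 (0.064), control 48 h replicate 1 (0.052) or control 48 h replicate 3 (0.058).

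CsA 48 h replicate 3 stood apart in these lists. Relative to the 12 h control mean the ER list was at 1.97, 1.19 and 0.09 on the CsA 48 h arrays and at 0.70, 0.24 and 0.49 on the CsA 12 h arrays. The ATF4 list was at 2.04, 2.16 and 0.02, against 0.90, 0.27 and 0.71, and the coat protein list at 0.84, 0.24 and 0.04, against 0.12, 0.09 and 0.15. None of the 3 lists was higher on that CsA array than on any CsA 12 h array. Medians without it were 1.14 for ER, 1.40 for ATF4, 0.50 for coat proteins, 0.62 for autophagy, -1.73 for DNA replication and -1.36 for metallothioneins. Without CsA 48 h replicate 1 they were 0.05 for ER, 0.26 for ATF4, 0.05 for coat proteins and 0.19 for p53. DNA replication was then at -0.62, metallothioneins at -0.54 and immediate early genes at -0.16. The ATF4 median was 0.21 and the p53 median 0.50 without CsA 48 h replicate 2.

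**Figure D3:**
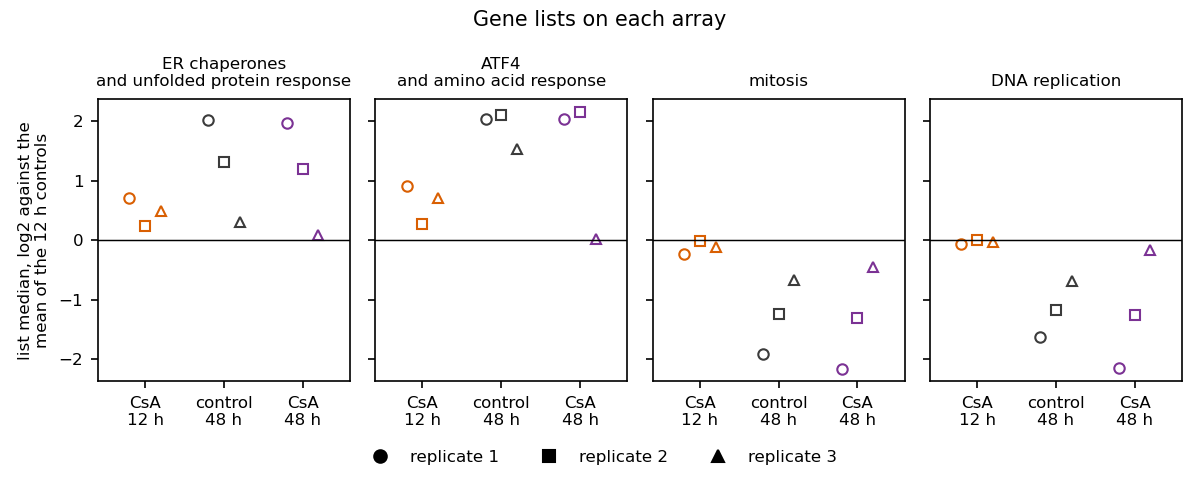
Median log2 level of the ER, ATF4, mitosis and DNA replication lists on each array, relative to the mean of the 12 h control arrays. The ATF4 list lay between 1.54 and 2.11 on the control 48 h arrays, and at 2.04, 2.16 and 0.02 on the CsA 48 h arrays.

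Limma called 1496 genes between CsA 48 h and CsA 12 h, 707 higher and 789 lower, of which 220 and 203 changed by at least 1 on the log2 scale. Higher and lower genes numbered 278 and 240 without CsA 12 h replicate 1, 291 and 291 without replicate 2 and 203 and 215 without replicate 3. They numbered 273 and 278 without CsA 48 h replicate 1, 379 and 399 without replicate 2 and 2097 and 1826 without replicate 3. With only the 6 arrays of the 2 groups they numbered 17 and 13. Across the 10650 genes, which are not independent replicates, the time changes in control and under CsA had Pearson's r = 0.91 and Spearman's rho = 0.90. Signs matched in 85.4%. These comparisons share no array, but share each gene's spread and paired replicates, so independent lists are no fair baseline. Called higher in both were 594 (87.4 for independent lists) and lower 676 (106), with 0 in opposite directions. The CsA effects at 12 h and 48 h, also sharing no array, had r = -0.07 and rho = 0.0046, and 50.2% had the same sign. That r ran from -0.25 without CsA 48 h replicate 1 to 0.27 without replicate 3. Genes shared by the time changes numbered 191 higher and 200 lower without CsA 12 h replicate 3. They were 1588 and 1493 without CsA 48 h replicate 3, with the other arrays between.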

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

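Chosen only after the result was seen were the test of single pairs in the first pattern, the test of CsA 48 h replicate 3 alone in the second, and the fits of the 12 h arrays alone with the pairs as a block.

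CsA effects at 12 h and 48 h differed for 5 lists by a test of the difference itself. They were ER chaperones (adjusted p = 1.86e-05), the ATF4 response (5.31e-22), tRNA synthetases (1.34e-05), cholesterol genes (3.35e-06) and glycolysis (0.018). Each was at adjusted p = 0.93 with an estimated correlation. Pair medians of 3 other lists all had opposite signs at the 2 times. By chance such signs come up for 3.12% of single genes, not of lists. Over all arrays immediate early genes were at -0.02 at 12 h and -0.19 at 48 h. Differences of effects were -0.22 for fatty acid synthesis, -0.087 for autophagy and lysosome and -0.29 for immediate early genes. Left-out arrays moved all 3. Fatty acid synthesis was at -0.13 without CsA 12 h replicate 2, 3.70e-04 without CsA 48 h replicate 1, -0.11 without control 12 h replicate 3, and -0.37, -0.11 and -0.04 without control 48 h replicates 1, 2 and 3. Autophagy and lysosome was at -0.04 without CsA 12 h replicate 1, -0.16, -0.14 and -0.01 without CsA 48 h replicates 1, 2 and 3, and -0.18 without control 48 h replicate 3. Immediate early genes were at 0.09 and -0.44 without CsA 48 h replicates 1 and 2, and -0.07 without control 48 h replicate 3. Opposite signs do not test the difference, which camera did without the block (adjusted p = 0.14, 0.059 and 0.11).

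Of 97 named genes of the CsA comparisons 19 (19.6%) went in opposite directions at the 2 times in every pair, against 566 (5.31%) of all 10650 tested genes. Many of the named genes were picked for a large statistic or as members of called lists, so the share given above for chance is no measure for them. Differences of log2 effects, 48 h minus 12 h, were -0.89 for ACSS2, -2.47 for ATF3, -2.69 for CTH, -1.72 for DDIT3, -1.19 for GARS1, -1.69 for HERPUD1, -0.72 for HSD17B7, -0.54 for INSIG1, -1.12 for MANF, -1.08 for MTHFD2, -0.77 for MVD, -1.60 for NIBAN1, -0.47 for SQLE, -1.67 for STC2, -0.61 for TARS1 and -1.14 for XBP1. For RTKN2, SHROOM2 and SOX9 they were 0.93, 0.92 and 1.11. Of the 19 values 12 moved by over 1.5 times without CsA 48 h replicate 3. Without it they were -1.29 for ATF3, -1.30 for CTH, -0.44 for DDIT3, -0.41 for GARS1, -0.64 for HERPUD1, -0.34 for HSD17B7, -0.46 for MANF, -0.71 for MTHFD2, -0.49 for NIBAN1, -0.89 for STC2, -0.30 for TARS1 and -0.72 for XBP1. Other arrays moved 3 genes as much: INSIG1 was at -0.35 without control 48 h replicate 3, MANF at -0.61 without control 48 h replicate 1 and -1.78 without control 48 h replicate 3. SQLE was at -0.25 without CsA 48 h replicate 1, -0.76 without CsA 48 h replicate 2 and -0.73 without control 48 h replicate 1. These fits drop an array and keep its partner in the pair, and the MANF pair differences at 48 h were -0.26, -0.33 and -0.28. The rule of opposite signs does not test a difference, and limma's test of the difference called 0 genes.

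The first pattern weighed is the higher ER and ATF4 lists under CsA at 12 h. The tables argue against a single array or pair as its source, since the smallest of the 6 list medians (2 lists in 3 pairs) was 0.41. Array scaling cannot be judged this way, because GCRMA had already normalised the arrays by quantiles, which keeps the all-gene difference small. That median difference was -0.014, and the list medians were 0.50 and 0.67 after centring each array. RNA quality is argued against. The difference between 3' and 5' probe sets of ACTB differed by -0.0089 on average between CsA and control, with overlapping ranges. For the time comparisons RNA quality stays open: that difference was 1.04, 1.01 and 0.83 in control 12 h and 1.22, 1.20 and 0.98 in control 48 h, and 0.99, 1.00 and 0.87 in CsA 12 h and 1.44, 1.05 and 0.92 in CsA 48 h. For the 12 h pattern CsA itself stays open, as does a difference in handling between CsA and control cultures, which was not tested. For the 12 h genes, 10 splits of 6 arrays are too few for a share under 0.05 (0 genes called, highest other split 0), as are the 4 splits that part the pairs in the 12 h arrays alone with trend and robust moderation (127 genes, highest other 0).

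The second pattern is the lower ATF4 list under CsA at 48 h. It may come from CsA 48 h replicate 3 alone: without that array the list's median was 0.056, against -0.49 with it, and it was -0.03 without both 48 h arrays numbered 3. A wrong time label is argued against, since over 2715 genes called in controls outside the stress lists that array had moved from the 12 h CsA mean with a slope of 0.37 on the control time change, against 1.09 and 0.87 for the other CsA 48 h arrays and -0.07 to 0.08 for the 12 h arrays. A swap with control 48 h replicate 3 cannot be told apart, because 47.5% of 61 genes that differed beyond 0.5 one way in the other pairs had that sign in the third pair. The slope of 0.37 also goes with a culture that had gone less far along the time change, which stays open.

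For the 48 h genes, 10 splits are again too few for a share under 0.05 (0 genes called, and 10 of 10 splits gave as many). Other splits called up to 513 genes, which points to a structure of the samples: the splits with 443 and 513 genes set CsA 48 h replicates 1 and 2 with control replicate 1, and CsA replicate 1 with control replicates 1 and 2, against the rest, which hold both arrays numbered 3. With the pairs as a block 0 genes were called at 48 h. For the difference between the CsA effects 0 genes were called, so all 100 of 100 splits must give as many, which tests nothing (highest other split 3). The time comparisons in controls (2749 genes, highest other 0) and under CsA (1496 genes, highest other 0) also have 10 splits each, too few for a share under 0.05, of which 1 gave as many, the real one.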

How the results depend on the processing

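The fits of the 6 arrays of a time, the fit without the 48 h arrays numbered 3 and the blocked list tests with an estimated correlation and by fry were chosen after seeing the data. Of 3944 values of 145 list results under the alternatives, 3293 kept direction and side of the threshold, 240 lost a call, 147 gained one, 248 uncalled ones changed sign and 16 changed direction with a call on either side. Of 5481 values of 232 named gene results, 5107 kept both, 145 lost a call, 107 gained one, 122 uncalled ones changed sign and 0 changed direction with a call. Genes below 4 lie near the background of the arrays, so a fall to or rise from such a level is a rough value. Where a value changed, the cause was not tested, except that a stricter threshold or a minimum change calls fewer genes and fewer arrays leave fewer degrees of freedom by construction.

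With the pairs as a replicate block within time, 3 genes were higher at 12 h and 9 lists were called for the difference between the CsA effects. Blocked list tests with an estimated correlation called 1 list at 12 h, 0 at 48 h and 0 for the difference, and fry with the block called 1, 0 and 2. In the 6 arrays of that time alone with the pairs as a replicate block, 5 genes were higher at 12 h, and with trend and robust moderation 102 were higher and 25 lower. There an estimated correlation called 0 lists at 12 h and 0 at 48 h, and fry 0 and 0. The block within time changed no call beyond those given here and in the results. It gives no value for the time comparisons, because its pairs lie within a time. With the replicate number as a block over all 12 arrays, 1087 genes were higher and 1292 lower with time under CsA, and 907 higher and 1117 lower were shared by both time comparisons.

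Camera with an estimated correlation called 0 lists in each of the 5 comparisons. Fry called 0 lists at 12 h, 0 at 48 h, 0 for the difference, 3 with time in controls and 3 under CsA. Without the filter 1 gene was higher at 12 h, 871 were higher with time in controls, 464 higher and 524 lower under CsA, and 387 higher and 450 lower in both. The filter at 6 called 8 lists for the difference, as did trend and robust moderation. Testing all probe sets called 2181 higher and 2577 lower in controls and 1096 and 1310 under CsA. An adjusted p under 0.01 left 409 higher and 417 lower in controls and 148 and 157 under CsA, and treat against 0.5 left 80 and 48, and 5 and 4. With only the arrays of the 2 groups 1 gene was higher at 12 h (CREB3L2), 17 were higher and 13 lower with time under CsA, and 17 higher and 12 lower in both.

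With estimated array weights 2991 genes were higher and 2993 lower with time in controls, 361 were higher under CsA, 348 were higher in both, and 9 lists were called for the difference. There DNA replication, CsA against control at 48 h, turned to lower (adjusted p = 6.11e-04), as it did for the difference (0.012). Without both 48 h arrays numbered 3, 2531 genes were higher and 2350 lower in controls, 2464 and 2063 under CsA and 2084 and 1805 in both. There r of the CsA effects was 0.12, DNA replication turned to lower at 48 h (adjusted p = 1.18e-06) and for the difference (9.20e-04), and the tRNA synthetases turned to higher with time under CsA (0.039).

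Leaving out each array in turn gave 0 to 0 genes at 12 h, at 48 h and for the difference, in either direction. Lists called numbered 5 to 9 at 12 h, 4 to 14 at 48 h, 5 to 10 for the difference, 6 to 12 in controls and 6 to 15 under CsA. With time in controls 655 to 2002 genes were higher and 629 to 2042 lower, under CsA 203 to 2097 and 215 to 1826, and in both 191 to 1588 and 200 to 1493. The r of the CsA effects ran from -0.25 to 0.27 and that of the time changes from 0.82 to 0.93. Directions changed at 48 h without CsA 48 h replicate 1 for coat proteins (adjusted p = 0.31) and mitosis (8.80e-05), and without CsA 48 h replicate 3 for ER (0.0028), ATF4 (0.54), tRNA synthetases (0.17) and DNA replication (1.09e-10). They changed without control 48 h replicate 1 for ER (adjusted p = 0.032) and without control 48 h replicate 3 for coat proteins (0.95) and mitosis (0.0050). For the difference they changed without CsA 48 h replicate 3 for DNA replication (adjusted p = 2.99e-07) and mitosis (7.36e-05). Over all 12 arrays left out, the adjusted p of these lists at 48 h ran from 3.50e-05 to 0.90 for ER, 2.27e-11 to 0.54 for ATF4, 0.0011 to 0.23 for tRNA synthetases, 3.84e-05 to 0.95 for coat proteins, 1.09e-10 to 0.83 for DNA replication and 1.22e-08 to 0.92 for mitosis. For the difference it ran from 2.99e-07 to 0.91 for DNA replication and 2.97e-05 to 0.91 for mitosis.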

Other observations

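The test of a shared control array and the test on TXNIP below were written before their results, and the genes named in the first paragraph were chosen after their values were seen.

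Among genes of lists not called without the block, IFI44L and HBEGF differed at 48 h in the same direction in every pair, neither past limma's test (adjusted p = 1.00 for each). IFI44L, an interferon-induced gene, differed by 1.18, with control 48 h replicate 2 below 4 and a value of 0.71 without it. HBEGF, a growth factor for the EGF receptor, differed by -0.76, and by -0.16 without CsA 48 h replicate 1. Their lists, interferon response and immediate early genes, were called with the pairs as a block.

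Lists outside the called ones had these median log2 differences at 12 h and 48 h: 0.04 and -0.04 for NRF2 targets, -0.03 and -0.03 for oxidative phosphorylation, -0.06 and -0.12 for TGF-beta targets, -0.01 and -0.03 for collagens, 0.05 and 0.02 for epithelial junctions, 0.0014 and -0.03 for kidney injury markers, -0.03 and -0.05 for cyclophilins with calcineurin and NFAT, -0.01 and -0.0019 for BCL2 family and caspases, 0.01 and 0.0088 for drug efflux enzymes and -0.05 and 0.14 for glucocorticoid-responsive genes. None of these 10 lists was called in any comparison (camera with all arrays). Left-out arrays gave calls at 48 h for NRF2 targets (lower without control 48 h replicate 2, adjusted p = 0.049), oxidative phosphorylation (lower without CsA 48 h replicate 3, 0.027, or control 48 h replicate 2, 0.039), TGF-beta targets (lower without CsA 48 h replicate 3, 0.0049, or control 48 h replicate 1, 0.0086), collagens (lower without CsA 48 h replicate 3, 4.99e-04) and kidney injury markers (higher without CsA 48 h replicate 1, 0.018). Interferon genes at 12 h had a median of 0.01 (adjusted p = 0.17) and were called higher without CsA 12 h replicate 3 (0.0030) or control 12 h replicate 1 (0.00995), and hypoxia targets, with a median of 0.07 (0.17), without CsA 48 h replicate 3 (0.048). The 48 h medians were -0.02 for DNA replication, -0.06 for mitosis, 0.03 for p53 targets, -0.14 for hypoxia targets, -0.06 for fatty acid synthesis, -0.05 for autophagy genes and -0.05 for metallothioneins, and the 12 h medians were -0.06 for DNA replication, 0.02 for p53 targets, -0.01 for glycolysis, -0.03 for metallothioneins, -0.02 for immediate early genes and 0.01 for ribosomal proteins, all uncalled with all arrays and no block.

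At 48 h DNA replication was called higher without CsA 48 h replicate 1 (adjusted p = 6.09e-07) and lower without CsA 48 h replicate 3 (1.09e-10). Mitosis was called higher without CsA 48 h replicate 1 (adjusted p = 8.80e-05) or control 48 h replicate 3 (0.0050), and lower without CsA 48 h replicate 3 (1.22e-08) or control 48 h replicate 1 (0.0041). Metallothioneins were lower without CsA 48 h replicate 3 (adjusted p = 7.59e-04) and hypoxia targets lower without CsA 48 h replicate 1 (0.011). For the difference between the CsA effects, DNA replication was called higher without CsA 48 h replicate 1 (adjusted p = 4.75e-06) and lower without CsA 48 h replicate 3 (2.99e-07). Mitosis was higher without CsA 48 h replicate 1 (adjusted p = 2.97e-05) or control 48 h replicate 3 (0.0019), and lower without CsA 48 h replicate 3 (7.36e-05). Coat proteins were lower without CsA 48 h replicate 1 (adjusted p = 0.0025) or control 48 h replicate 3 (0.032). Metallothioneins (adjusted p = 0.0057), TGF-beta targets (0.042) and collagens (0.0057) were lower without CsA 48 h replicate 3. NRF2 targets were lower without control 12 h replicate 1 (adjusted p = 0.049) or control 48 h replicate 2 (0.031).

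Ribosomal proteins were higher for the difference without control 12 h replicate 1 (adjusted p = 0.047) or control 48 h replicate 2 (0.045), and oxidative phosphorylation higher without control 48 h replicate 3 (0.049). With time in controls the tRNA synthetases were higher without CsA 48 h replicate 3 (adjusted p = 0.0085) or control 48 h replicate 3 (0.043), and epithelial junctions higher without control 48 h replicate 3 (0.041). Metallothioneins were lower in controls without CsA 48 h replicate 1 (adjusted p = 0.029), CsA 48 h replicate 3 (0.019) or control 48 h replicate 3 (0.0087), and oxidative phosphorylation lower without control 48 h replicate 3 (0.015). With time under CsA oxidative phosphorylation was lower without CsA 48 h replicate 3 (adjusted p = 0.026), control 48 h replicate 2 (0.045) or control 48 h replicate 3 (0.038). Without CsA 48 h replicate 3 collagens were lower (adjusted p = 0.030) and hypoxia targets higher (0.023) with time under CsA. With all arrays none of these results was called.

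Few markers of cell types were past the filter. For the cells' own type they were 4 proximal tubule genes of 26, and for other types 3 distal nephron, 3 podocyte, 2 endothelium and 0 leukocyte genes, too few for a test. Markers of fibroblasts and pericytes, 6 of 12 past the filter, had medians of 0.0018 at 12 h and -0.25 at 48 h.

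A hypothesis from these data is that CsA at 12 h moved genes the way culture time moved them in controls. The CsA effect of each pair was set against the control time change computed without that pair's control array, and across genes, which are not independent replicates, the correlations were 0.38, 0.33 and 0.34, the lowest 0.33. Without the stress lists they were 0.35, 0.30 and 0.30 over 10559 genes. Shared control arrays are argued against as the whole source, and the data do not say whether CsA cells may have been further along in culture or responded in a similar way.

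Another hypothesis is that the ER and ATF4 genes that rose with time in controls did so because glucose ran short. TXNIP, whose transcription falls when glucose is short, fell by 5.16 in controls, as the hypothesis needs, but ARRDC4, the other gene chosen for the test, was not past the filter, so this could be one candidate explanation among several and the test leaves it open.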
